A study of Mus musculus with 14 samples.

How the data were processed

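RNA of mouse splenic CD4+ T cells was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 1 array for each of 7 inhibitors at 2 h and at 8 h, 14 in all. The deposited values are 1 intensity per probe set and array, and the submitters' processing notes name Affymetrix Power Tools and RMA without versions. All values were positive, from 4.78 to 22879, with medians of 109 to 121 per array, so they were read as linear and put on the log2 scale. The background correction, any further filter and the set of arrays normalized together are unknown. Pairwise Pearson r of the log2 values was between 0.980 and 0.998, and no pair of arrays was identical. Group, target label and time were taken from the sample titles and labels. Arrays without inhibitor were not used here.

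Of 24922 probe sets, 21425 carried 1 gene symbol (19752 symbols), 1399 carried several and 2098 none, and only the first kind was used. Symbols were checked against a table of RefSeq names from assembly GRCm38.p6, which held 21347 of the identifiers and changed 0 symbols. A gene was tested if its brightest probe set had a mean log2 intensity at or above the 40th percentile of those probe sets (6.29), which left 11761 genes. Jak3 and Isg15 have no probe set with that symbol alone and were not analysed here. The depth of an array is its signal over background, and dim genes were left out by the filter. The number of arrays limits the precision.

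Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For 8 h against 2 h and for each inhibitor against the others or another, 1 additive fit of inhibitor and time was used (lmFit and eBayes with trend=TRUE, 6 residual degrees of freedom). Its residual is the interaction of inhibitor and time plus noise, since no array was repeated. The target classes were compared on 1 value per inhibitor, its 2 h value, its 8 h value, their mean or their difference (4 inhibitors against 3, 5 residual degrees of freedom). The PAN inhibitor was taken to include JAK1 and JAK3. Adjusted p are Benjamini-Hochberg values over all genes tested within a comparison, with a threshold of 0.05. The 5 inhibitors naming JAK1 or JAK3 were compared with the other 2 in the same way.

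Gene lists (27) and marker lists of cell types (9) were written down before the data were examined, as were the comparisons and the rule for named genes, and the 30 lists with at least 5 tested members were used. List means were compared between classes by exact permutation (35 or 21 arrangements) and between times by exact sign-flip tests of the 7 pairs, one-sided for the type I interferon list in the comparison of JAK1 or TYK2 and for the STAT5-induced list in the comparison of JAK1 or JAK3. Camera compared each list with all other genes at a preset correlation of 0.01 and again with an estimated one, and fry tested whether the members move on balance one way, without comparing them with other genes. A list member count is given over all genes and adjusted over the list alone. 1 list, of skeletal muscle genes, was added after the data were seen. Intervals of list means between inhibitors are 95% intervals of the additive fit.

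Named genes are the 10 largest in each direction among those that passed with the same sign in all 7 inhibitors (time) or without overlap (classes), or the 5 with the smallest p if none passed. For single inhibitors they are the 5 largest in each direction or the 3 with the smallest p. To these come up to 4 members per list with the largest moderated t, and a fixed set of JAK, STAT, SOCS and interferon genes, given for time and where a comparison concerns them. Gbp11, Ifi208, Trim25, Ppbp and the cell markers Cd8a, Cd8b1, S100a8 and Ncr1 lie outside the rule and were named after their values were seen.

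Alternatives tried were quantile normalization, median centring, no filter or one at the 60th percentile, the mean of a gene's probe sets, no variance trend, robust moderation, an offset of 50 before the log, a fold change of at least 1.5, no pairing by inhibitor, the inhibitor as a random block, the JAK3 inhibitors averaged, the TYK2 or PAN inhibitor left out, the median or scaled members of a list, and each inhibitor left out in turn. Cyclic loess and leaving out the 8 h array of the JAK1 inhibitor were chosen after seeing the data.

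The steps were tested on simulated data with 11761 genes, 200 of them changed. At a log2 change of 1, the comparison of times recovered 100% of the changed genes, the JAK1 inhibitor against the rest 97.0%, the TYK2 inhibitor 100%, the class comparison of means 97.0%, at 2 h 100%, at 8 h 95.5%, and that of the 8 h minus 2 h difference 92.5%. At a log2 change of 0.5 these were 92.5%, 71.6%, 74.6%, 85.1%, 86.6%, 49.3% and 34.3%, and at 2 each was 100%. Unchanged genes called were 8, 10, 10, 14, 13, 2 and 7 in that order. A list of 62 genes shifted by -0.5 was called, and 0 other lists were. The simulated genes were drawn independently of each other. The run therefore does not test camera at its preset correlation on lists whose members move together.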

Results

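Mouse splenic CD4+ T cells were activated for 48 h with CD3/CD28 beads and then given interferon alpha (100 U/ml) with 1 of 7 JAK inhibitors for 2 h or 8 h, and 14 arrays measured their RNA. The sample titles read IFN.3404 (target label JAK1), IFN.6221 (JAK1/2), IFN.6222 (PAN), IFN.2485 (TYK2), IFN.3885 (JAK2), IFN.6226 and IFN.6228 (both JAK3), where IFN is the interferon that every sample got and the digits are the code of the inhibitor. Each inhibitor was used at its IC80 and is named below by its target label, the JAK3 pair by the titles. There was 1 array per inhibitor and time and no replicate, so no p measures the spread between repeated cultures. Between target classes, p rests on the spread between inhibitors. Between times, or for 1 inhibitor against others, it rests on how unevenly the inhibitors changed from 2 h to 8 h, plus noise. Arrays without inhibitor or without interferon were not analysed here, so each value below is a difference between inhibitors or between times. Cd3e (a chain of the T cell receptor complex) was at a mean log2 intensity of 12.37 and Cd4 at 11.82. Of the markers of other cells, Cd8a was at 6.81 and Cd8b1 at 8.99, Lyz2 of macrophages at 7.12 and Ctss at 9.25, S100a8 of granulocytes at 4.32, Ncr1 of NK cells at 4.47, Ms4a1 of B cells at 8.57 and Cd79a at 8.04, and Cd74, of antigen-presenting cells, at 10.14. Intensities of different probe sets do not rank the cell types. The 8 h array of the JAK1 inhibitor stood farthest from the other arrays of its time (mean Pearson r 0.990 across genes, which are not independent replicates). The number of arrays limits the precision of every value.

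The type I interferon receptor signals through JAK1 and TYK2, so the 4 inhibitors whose labels name JAK1 or TYK2 (JAK1, JAK1/2, PAN, taken to include JAK1, and TYK2) were set against the 3 that name only JAK2 or JAK3. At 2 h the genes of the type I interferon response were lower with the former. Rsad2, the antiviral protein viperin, fell by 1.96 on the log2 scale (SE 0.15, 3.88-fold, n = 4 and 3 inhibitors, limma adjusted p = 1.22e-04). Oasl2, of the oligoadenylate synthetase family, differed by -1.72 (SE 0.17), Mx1, an interferon-induced antiviral GTPase, by -1.56 (SE 0.17), and Parp12, an ADP-ribosyltransferase, by -1.30 (SE 0.11). Ifit3, which binds viral RNA complexes, had the largest difference, -2.21 (SE 0.28, 4.62-fold, adjusted p = 0.00213). Of the 62 list members tested, 43 were lower and none higher over all genes tested, and 59 were lower when adjusted over the list alone. The list mean was 8.83 ± 0.32 (SD, n = 4) against 9.73 ± 0.04 (n = 3), a 1.87-fold difference without overlap, with a one-sided exact permutation p of 0.0286. That is the smallest p the 35 arrangements allow (adjusted p = 0.428 over 30 lists). The other lists were tested two-sided, where the exact p cannot fall below 0.0571 (0.0952 for 5 inhibitors against 2). An adjusted exact p between classes, here or below, therefore could not pass the threshold. The set test camera gave an adjusted p of 9.44e-134 at a preset correlation, and the adjusted p = 0.105 with an estimated correlation; fry gave 0.0334.

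Other genes moved with them at 2 h. In all, 82 genes were lower with the inhibitors naming JAK1 or TYK2 and 0 were higher (limma, 484 at an unadjusted p under 0.05), of which 43 belong to the type I list, 4 to the list of interferon gamma inducible GTPases and antigen presentation, and 35 to neither. None of the 82 had values that overlapped between the classes, and 592 genes in all had none (5.03% of those tested, where chance gives 5.71%). Stat2, which carries the interferon signal to the nucleus, fell by 1.12 (SE 0.17, adjusted p = 0.00629), Irf7 differed by -1.50 (SE 0.33, adjusted p = 0.0728) and Irf9 by -0.38 (SE 0.10, adjusted p = 0.234). In the GTPase list, Iigp1, Irgm1, Gbp4 and Gbp7 were lower of 22 tested (16 adjusted over the list alone), with Iigp1, an immunity-related GTPase, at -1.41 (SE 0.23). Camera gave this list an adjusted p of 1.75e-24, with adjusted p = 0.105 with an estimated correlation, and fry 0.0849. In the BCL2 family and cell death list, 2 of 14 members fell, Tnfsf10 (the death ligand TRAIL) by 0.64 (SE 0.10) and Casp4 (a caspase that senses bacterial lipopolysaccharide) by 0.34 (SE 0.07); the same 2 passed when adjusted over the list alone. Camera gave it 0.00108, the adjusted p = 0.105 with an estimated correlation, and fry 0.0334. Robust variance moderation called 46 genes and ended the calls of Ifit3, Usp18, Ifit1, Slfn5, Dhx58, Mx2 and Cmpk2, and of Stat2 and Iigp1, quantile normalization ended those of Usp18, Ifit1, Irgm1, Gbp4 and Gbp7, and Casp4 did not pass with no filter on dim probe sets. The count was 28 without IFN.6228 and 35 without JAK2, where Stat2 and Tnfsf10 did not pass, 48 without IFN.6226 and 33 with the JAK3 inhibitors averaged.

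**Figure D1:**
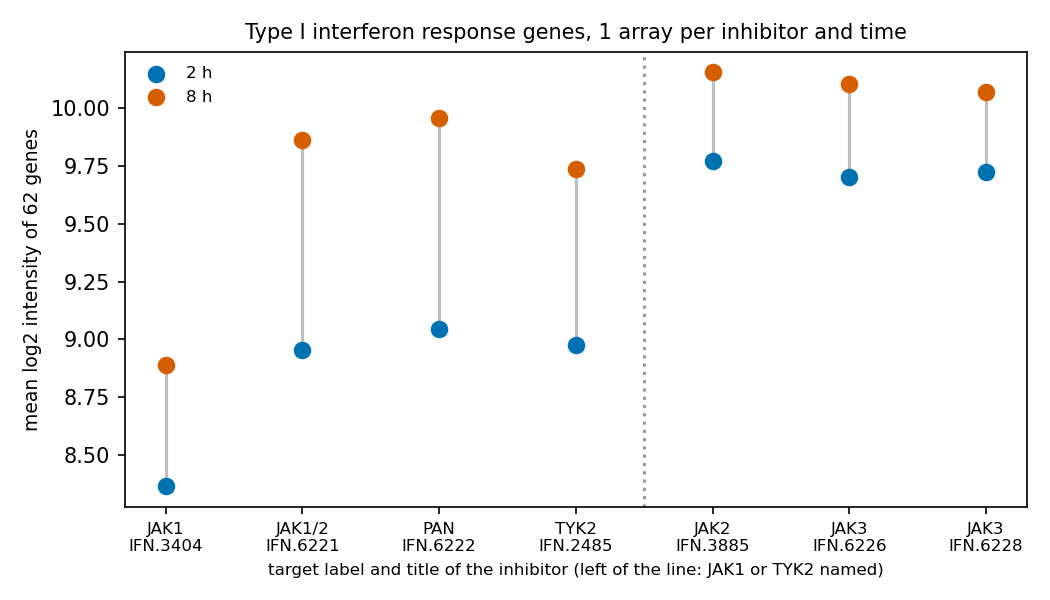
Mean log2 intensity (y axis) of the 62 type I interferon response genes for each inhibitor (x axis), with 1 point per array at 2 h (blue) and at 8 h (orange) and a line joining them. At 2 h the inhibitors left of the dotted line lie between 8.36 and 9.04 and those right of it between 9.70 and 9.77; the JAK1 inhibitor is the lowest at both times.

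At 8 h the classes were closer in the type I list. The type I list was at 9.61 ± 0.49 (SD, n = 4) against 10.11 ± 0.04 (n = 3), a 1.41-fold difference without overlap (one-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.245). Without the JAK1 inhibitor the difference went from -0.50 to -0.26. No single gene passed at 8 h (limma, 0 genes, 1834 at an unadjusted p under 0.05), and no list member passed when adjusted over the list alone. Over all genes, more had values without overlap than at 2 h: 2256 genes (19.2% of those tested, where chance gives 5.71%). Genes move together on the same arrays, so this share is no test. The median of all genes in this comparison was -0.08, against 0.01 at 2 h. Whether the scaling of whole arrays made this share was not tested. Ifit3 was at -1.23 (SE 0.45), Mx1 at -1.04 (SE 0.36) and Ifitm3, which blocks viral entry, at -0.72 (SE 0.14), each with an adjusted p of 0.307; the other genes with the smallest p were Olfr316 (0.82), Gpr6 (0.43), Gm10777 (-0.64) and Frem2 (0.47). Camera gave the type I list 4.51e-11, with adjusted p = 0.974 with an estimated correlation.

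For the mean of both times, the type I list differed by -0.70 (9.22 ± 0.40, n = 4, against 9.92 ± 0.04, n = 3, one-sided exact permutation p = 0.0286, adjusted p = 0.428). No gene passed over all genes (limma, 0, 1234 at an unadjusted p under 0.05), but 59 of the 62 members were lower when adjusted over the list alone. Values did not overlap between the classes in 1432 genes (12.2% of those tested, where chance gives 5.71%). The median of all genes was -0.03 here, and this share is no test either. Camera gave the list 1.24e-39, with adjusted p = 0.938 with an estimated correlation. Oasl1 (-0.46, SE 0.07), Ifitm3 (-0.53, SE 0.08), Cxcl10, a T cell attracting chemokine (-0.48, SE 0.07), Tor3a (-0.32) and Tmem140 (-0.40) had the smallest p, with adjusted p from 0.165 to 0.239. Without the JAK1 inhibitor 97 genes were lower and 1 higher, 48 of the 98 from the type I list. The fit of all 14 arrays with the inhibitor as a random block called 64 genes, but its consensus correlation was -0.023, so it counts the 2 h and 8 h arrays of an inhibitor almost as independent.

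The gap in type I interferon genes narrowed between the times. The type I list rose by 0.78 ± 0.18 from 2 h to 8 h with the inhibitors naming JAK1 or TYK2 (SD, n = 4) and by 0.38 ± 0.03 with the others (n = 3), without overlap; the two-sided exact permutation p of 0.0571 is the smallest possible (adjusted p = 0.513). Usp18, the protease that removes ISG15 and restrains the interferon receptor, rose by 1.52 ± 0.14 (n = 4) against 0.46 ± 0.04 (n = 3), a difference of 1.06 (SE 0.10, adjusted p = 4.83e-04). Ifit1, which binds foreign RNA ends, differed by 1.00 (SE 0.11, adjusted p = 0.00164), and Irf7, the factor that amplifies interferon transcription, by 0.83 (SE 0.12). The 12 genes that passed also included Slfn5, Rtp4, Dhx58, Oas3, Slfn8 and Trim25 of the type I list, Irgm1, and Gm12250 and Ifi208 of neither list, all with the larger rise in the former class (0 the other way; limma, 1186 at an unadjusted p under 0.05). Of the 62 members 56 had a positive difference and 36 passed when adjusted over the list alone; camera gave 2.82e-41, with adjusted p = 0.331 with an estimated correlation. Ifit3 (0.98, SE 0.22), Stat2 (0.60, SE 0.12) and Mx1 (0.52, SE 0.22) did not pass. The median of all genes in this comparison was -0.09 as deposited and 0.05 after median centring, where 25 genes passed. The count was 2 without JAK2, JAK1/2, IFN.6226 or IFN.6228 or with the JAK3 inhibitors averaged, 41 without the JAK1 inhibitor, 24 after quantile normalization and 7 with an offset before the log.

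The type I interferon list was lowest with the JAK1 inhibitor of the 7. Against the other 6 inhibitors, with time in the fit, Rtp4, a receptor transporter induced by interferon, fell by 2.60 (SE 0.19, 6.07-fold, n = 2 arrays against 12, adjusted p = 4.72e-06). Ifit3 fell by 2.43 (SE 0.24), Usp18 by 2.43 (SE 0.21), Ifit1 by 2.12 (SE 0.21) and Rsad2 by 1.98 (SE 0.24). Irf7 fell by 1.96 (SE 0.18), Mx1 by 1.74 (SE 0.19), Stat2 by 1.12 (SE 0.14) and Irf9, a DNA-binding factor of the interferon response, by 0.62 (SE 0.07). In the type I list 56 of 62 members were lower (60 adjusted over the list alone) at a mean of -1.05. Camera gave 2.01e-52, with adjusted p = 0.234 with an estimated correlation, and fry 0.00316. In the GTPase list 13 of 22 were lower (14 adjusted over the list alone), among them Iigp1 at -1.86 (SE 0.14), Irgm1 at -1.37 (SE 0.15), Gbp4 at -0.75 (SE 0.07) and the immunoproteasome subunit Psmb9 at -0.67 (SE 0.07); camera gave 2.43e-10, with adjusted p = 0.234 with an estimated correlation, and fry 6.91e-04. Tnfsf10 fell by 0.79 (SE 0.09). In the oxidative phosphorylation list 12 of 27 were lower (17 adjusted over the list alone), with Atp5a1 of the ATP synthase at -0.46 (SE 0.05) and Cox5a of cytochrome c oxidase at -0.41 (SE 0.08). The list mean was -0.19 as deposited and -0.11 after cyclic loess. Camera gave 5.13e-05, with adjusted p = 0.701 with an estimated correlation, and fry 0.0104.

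The JAK1 inhibitor was also the one with the most genes apart from the rest: 801 lower and 113 higher of 11761 tested, 56 of the 801 in the type I list where 4.22 would fall by chance. Its 8 h array is 1 of 3 with a higher mean of skeletal muscle genes (7.55 to 7.63, against 6.90 to 7.18 in the other 11), the others being those of the JAK1/2 inhibitor. It had the lowest upper quartile of intensity (398) and, against the other 6 arrays at 8 h, a median difference of 0.06 in the dimmest of 5 brightness groups and -0.23 in the next to brightest. The split of directions followed the scaling: 776 higher and 762 lower after quantile normalization, 774 and 783 after cyclic loess, and 888 and 569 after median centring, which moved the median of all genes from -0.05 to 0.05. Without that array 232 genes passed (25 higher, 207 lower), 174 of them among the 914 and 43 from the type I list. The JAK1 inhibitor then had 1 array, so the spread in that fit came from the other inhibitors alone. With both its arrays, the count for the JAK1 inhibitor was 1528 without JAK2, 569 without PAN, 458 without IFN.6226, 453 without TYK2 and 360 without IFN.6228. Among the higher genes, Rnu12 (a small nuclear RNA) was at 1.29 (SE 0.21) and kept its call without the array, while AY036118 (1.40), the small nucleolar RNA Snora44 (0.76), Gm10785 (0.69) and the NKG2D ligand H60b (0.66) did not pass without it.

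With the JAK2 inhibitor 9 genes and the STAT5-induced list were higher. Against the other 6 inhibitors, Cish, a STAT5-induced inhibitor of cytokine signalling, rose by 1.06 (SE 0.14, 2.08-fold, n = 2 arrays against 12, adjusted p = 0.0211), Socs2 of the same family by 0.79 (SE 0.09, adjusted p = 0.00781) and Socs1 by 0.63 (SE 0.09, adjusted p = 0.0262). The 9 genes that passed, all higher, also held Oasl2 (1.22, SE 0.20), Gm4951 (0.85), Lgals3bp (0.65), Mov10 (0.52), and the guanylate-binding GTPases Gbp5 (0.52) and Gbp11 (0.53), with 547 genes at an unadjusted p under 0.05. The STAT5-induced list, which follows interleukin-2, was higher by 0.29, with 2 of 32 members called, 19 when adjusted over the list alone and 32 of 32 positive; camera gave 2.09e-30, with adjusted p = 0.0358 with an estimated correlation, and fry 0.0131. In the list of JAK-STAT feedback inhibitors 3 of 18 members were called (5 adjusted over the list alone), at a mean of 0.23, with camera at 4.96e-04, adjusted p = 0.254 with an estimated correlation, and fry at 0.0675. Il2ra, the high-affinity interleukin-2 receptor chain, was at 0.28 (SE 0.07, adjusted p = 0.124) and Osm, a cytokine, at 0.51 (SE 0.09, adjusted p = 0.0657). In the Th2 list none of 10 members passed over all genes and 7 did when adjusted over the list alone, with Ccr4 at 0.33 (SE 0.07) and Il4 at 0.57 (SE 0.13). Camera gave it 3.77e-10, with adjusted p = 0.0456 with an estimated correlation. The type I list was higher by 0.52 (3 of 62 called, 55 adjusted over the list alone; camera 1.14e-69, adjusted p = 0.0626 with an estimated correlation), and the GTPase list by 0.23 (1 of 22, and 10 higher and 1 lower adjusted over the list alone; camera 4.76e-13, adjusted p = 0.0475 with an estimated correlation). In the GTPase list the JAK2 inhibitor was above JAK1, JAK1/2, PAN and TYK2 by 0.21 to 0.59 in size. It differed from IFN.6226 by 0.04 (95% interval -0.09 to 0.16) and from IFN.6228 by 0.03 (-0.10 to 0.16). In the type I list it differed from these JAK3 inhibitors by 0.06 and 0.07. Of the 9 genes, only Cish and Socs2 passed against IFN.6226 or IFN.6228 (limma), so the higher interferon genes are not particular to the JAK2 inhibitor. After cyclic loess Socs2 (0.75, SE 0.09, adjusted p = 0.0422) and Osm passed and the other 8 did not, with Cish at 1.02 (SE 0.17, adjusted p = 0.116). The count was 1 after quantile normalization, 2 after median centring, 4 with no variance trend or without JAK1/2 or TYK2, 16 without PAN, 35 without IFN.6226, 51 without IFN.6228 and 81 without the JAK1 8 h array.

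**Figure D2:**
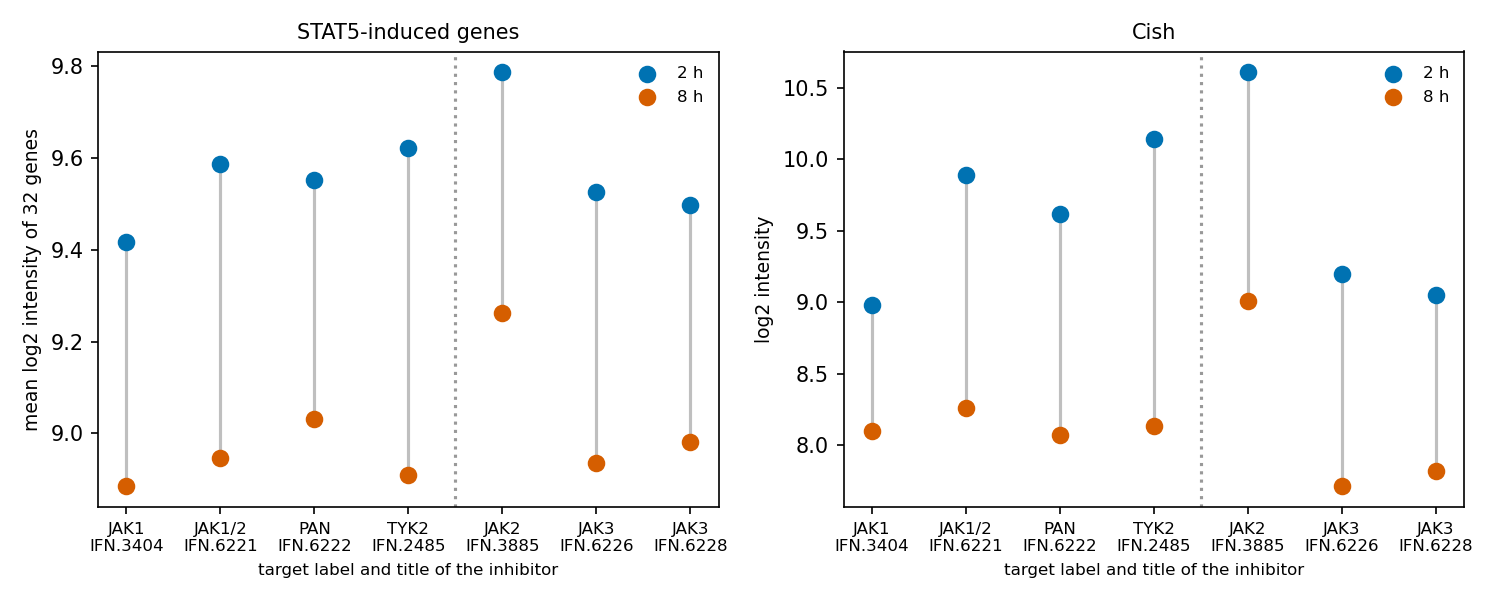
Mean log2 intensity of 32 STAT5-induced genes (left) and log2 intensity of Cish (right) for each inhibitor (x axis), 1 point per array at 2 h (blue) and 8 h (orange), joined by a line; the dotted line parts the labels naming JAK1 or TYK2 from the others. The JAK2 inhibitor is the highest in each at both times, with Cish at 10.61 at 2 h and 9.01 at 8 h.

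Receptors with the common gamma chain, such as that of interleukin-2, signal through JAK1 and JAK3, so the 5 inhibitors naming JAK1 or JAK3 were set against the JAK2 and TYK2 inhibitors. At 2 h the STAT5-induced list was at 9.52 ± 0.06 (SD, n = 5) against 9.70 ± 0.12 (n = 2), a difference of -0.19 without overlap (one-sided exact permutation p = 0.0476, the smallest of 21 arrangements, adjusted p = 0.408). Without the JAK2 inhibitor it was -0.11. The difference was -0.13 at 8 h (exact permutation p = 0.238) and -0.16 for the mean of both times (exact permutation p = 0.143), where the classes overlapped. For that mean camera gave 5.28e-12, with adjusted p = 0.479 with an estimated correlation, and 5 of 32 members were lower when adjusted over the list alone. No gene passed (limma, 0, 243 at an unadjusted p under 0.05). Cish differed by -0.80 (SE 0.20), Socs2 by -0.61 (SE 0.12), Lta by -0.24 (SE 0.06) and Tnfrsf9 by -0.24 (SE 0.07), each with an adjusted p of 0.999, and the others with the smallest p were Rasgef1a (0.37), Ccr9 (0.49), Fcgr3 (0.42) and Prnp (-0.30). At 2 h Cish was at 10.61 with the JAK2 and 10.14 with the TYK2 inhibitor, and at 9.89 with the JAK1/2, 9.62 with the PAN, 9.20 and 9.05 with the JAK3 and 8.98 with the JAK1 inhibitor.

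All inhibitors were compared in pairs, each at its own IC80, at the same times. For the mean of the type I list over both times, the JAK1 inhibitor was lower than each other by 0.73 to 1.34 in size (SE 0.18), the smallest against TYK2 at -0.73 (95% interval -1.17 to -0.30) and the largest against JAK2 at -1.34 (-1.77 to -0.90). These 6 pairs had adjusted p from 0.0022 to 0.0215 with fry. The intervals are not adjusted for the number of pairs. The JAK2 inhibitor was above JAK1/2 by 0.56 (interval 0.12 to 0.99, adjusted p = 0.0416 with fry) and above TYK2 by 0.61 (0.17 to 1.04, adjusted p = 0.0405), while the 0.46 above PAN (0.03 to 0.90) did not pass (adjusted p = 0.0695), and it differed from the JAK3 inhibitors by 0.06 (-0.38 to 0.50 for IFN.6226) and 0.07 (-0.37 to 0.50 for IFN.6228). IFN.6226 was above TYK2 by 0.55 (0.11 to 0.98, adjusted p = 0.0416 with fry). JAK1/2 differed from it by -0.50 (-0.93 to -0.06), which did not pass (adjusted p = 0.0533), and PAN and IFN.6226 differed by -0.40 (-0.84 to 0.03). These gaps were wider at 2 h than at 8 h. JAK2 minus PAN was 0.73 at 2 h and 0.20 at 8 h, and JAK2 minus JAK1/2 0.82 and 0.29. PAN minus IFN.6226 was -0.66 and -0.15. Pairs were not tested at single times. The SE holds this change with time, as it comes from the residual of the additive fit. The JAK1/2 and PAN inhibitors differed by -0.09 (interval -0.53 to 0.34), JAK1/2 and TYK2 by 0.05 (-0.38 to 0.49) and PAN and TYK2 by 0.14 (-0.29 to 0.58), so differences of that size stay possible. The inhibitors IFN.6226 and IFN.6228, which share a label, differed by 0.01 (-0.43 to 0.44), and in the STAT5-induced list by -0.01 (-0.14 to 0.12). In the STAT5-induced list the JAK2 inhibitor was above each of the other 6, by 0.23 to 0.38 (SE 0.05). By gene (limma), the JAK1 inhibitor differed from IFN.6228 in 712 genes, from IFN.6226 in 351, TYK2 in 304, JAK2 in 244, PAN in 86 and JAK1/2 in 44. Of the 712 genes, 646 were lower and 66 higher. The deviating 8 h array of the JAK1 inhibitor enters each of these counts. Their order is not that of the type I list, and they were not compared under another scaling or without that array. They therefore do not rank the inhibitors. The 2 genes between JAK2 and IFN.6226 were Cish (1.35, SE 0.19) and Socs2 (0.91, SE 0.12). The 3 between JAK2 and IFN.6228 were Cish (1.37, SE 0.19), Socs2 (0.90, SE 0.12) and Ppbp, a platelet chemokine (-2.31, SE 0.31). Atp2a1 was the 1 gene between JAK1/2 and IFN.6226 (1.32, SE 0.16). These few were named because they passed, after their values were seen. The other 12 pairs had 0 genes (limma), with 42 at an unadjusted p under 0.05 between IFN.6226 and IFN.6228 and 137 to 1221 in the rest.

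Any difference between the 7 inhibitors was found in 172 genes (limma moderated F-test, 1208 at an unadjusted p under 0.05), 48 of them in the type I list and 9 in the GTPase list. The count was 45 without JAK1, 102 without IFN.6228, 111 without TYK2 and 103 with no variance trend. With the JAK1/2 inhibitor only Atp2a1, the calcium pump of fast skeletal muscle, was higher than with the other 6 (1.04, SE 0.12, adjusted p = 0.00888; limma, 614 at an unadjusted p under 0.05), and it did not pass after median centring or without IFN.6226. The 15 measured muscle genes, a list written after the data were seen, had 14 higher there, at a mean of 0.51. With the TYK2 inhibitor no gene passed (limma, 0, 569 at an unadjusted p under 0.05). Il7r, the interleukin-7 receptor, was at -0.41 (SE 0.06), St8sia6 at -0.52 (SE 0.08) and Itga4, an integrin, at -0.37 (SE 0.06), with adjusted p from 0.0596 to 0.0806, and Il7r and St8sia6 passed after quantile normalization. Its type I list was at -0.19 (camera 3.94e-14, adjusted p = 0.327 with an estimated correlation). With the PAN inhibitor no gene passed (limma, 0, 38 at an unadjusted p under 0.05), and Il7r (0.19), Fos (-0.34) and Ssc5d (-0.31) had the smallest p. With the JAK3 inhibitors the type I list was higher than the rest by 0.45 (IFN.6226) and 0.44 (IFN.6228), with 51 of 62 members higher in each when adjusted over the list alone; camera gave 4.23e-74 and 5.88e-41, with adjusted p = 0.109 and 0.257 with an estimated correlation. The rest holds the JAK1 inhibitor, which differed from IFN.6226 and IFN.6228 by -1.28 and -1.27 in this list, while JAK2 differed by 0.06 and 0.07. No single gene passed with either JAK3 inhibitor (limma, 0 and 0, 375 and 811 at an unadjusted p under 0.05). Ifi213, of the interferon-inducible p200 family, was at 0.79 (SE 0.12) with IFN.6226 and 0.77 (SE 0.12) with IFN.6228, BC147527 at 0.63 and 0.72, Gm4951 at 0.75 with IFN.6226 and Ccnyl1 at 0.61 with IFN.6228. Cish was at -0.52 (SE 0.14) and -0.54 (SE 0.14).

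Between 2 h and 8 h the early activation programme fell with every inhibitor. Nr4a3, an orphan nuclear receptor induced by T cell receptor signalling, fell by 3.27 (SE 0.08, 9.62-fold, n = 7 pairs, adjusted p = 4.85e-12), while Il2 (interleukin-2) was at -2.69 (SE 0.07), Nr4a1 at -2.37 (SE 0.06) and Egr2, an activation-induced zinc finger factor, at -2.04 (SE 0.07), each lower in 7 of 7 inhibitors. In the list of early T cell receptor genes and cytokines 22 of 28 fell and 3 rose, at a mean of -0.93 ± 0.10 (SD, n = 7 pairs). Ccr8, a Th2 chemokine receptor, fell by 2.50 (SE 0.07), and 8 of 10 Th2 genes fell and 1 rose, with the hypoxia factor Epas1 at -1.45 (SE 0.12), the cyclic AMP factor Crem at -1.40 (SE 0.09) and the chemokine receptor Ccr4 at -0.87 (SE 0.05). In the STAT5-induced list 23 of 32 fell and 2 rose (23 and 3 adjusted over the list alone), at -0.58 ± 0.08 (n = 7 pairs), with the aryl hydrocarbon receptor Ahr at -1.63 (SE 0.06), Cish at -1.48 (SE 0.10), Socs2 at -1.47 (SE 0.07), the kinase Cdk6 at -1.39 (SE 0.06), the co-stimulatory receptor Tnfrsf4 at -1.02 (SE 0.04) and Il2ra at -0.81 (SE 0.05). Other large falls were in Fads2, a fatty acid desaturase (-2.60, SE 0.09), the phosphatase Dusp4 (-2.26), Spsb1 (-2.19), Pmepa1, a brake on TGF-beta signals (-2.09), and Egln3, an oxygen sensor (-1.99).

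Genes of biosynthesis fell with them. In the list of MYC targets and ribosome biogenesis 25 of 27 fell and 0 rose, at -0.84 ± 0.12 (SD, n = 7 pairs), with the spermidine synthase Srm at -1.39 (SE 0.07), Rcl1 at -1.27 (SE 0.06) and the nucleolar protein Nolc1 at -1.18 (SE 0.05). In the sterol synthesis list 23 of 25 fell and 0 rose, at -0.90 ± 0.17 (n = 7 pairs), with the sterol demethylase Cyp51 at -1.91 (SE 0.10), the desaturase Scd1 at -1.71 (SE 0.07) and the lanosterol synthase Lss at -1.67 (SE 0.08). In the ATF4 and amino acid list 21 of 25 fell and 2 rose, with the amino acid transporters Slc7a5 at -1.69 (SE 0.05) and Slc7a1 at -1.43 (SE 0.06) and the asparagine synthetase Asns at -1.52 (SE 0.08). In the glycolysis and hypoxia list 19 of 25 fell and 1 rose, with the hypoxia gene Bnip3 at -1.49 (SE 0.09) and the glycolytic enzymes Aldoc at -1.34 (SE 0.08) and Tpi1 at -1.08 (SE 0.06). Cell cycle genes went both ways. Of the G1 and S phase genes 24 of 28 fell and 0 rose, with E2f1, an S phase factor, at -0.58 (SE 0.07) and the replication helicase subunits Mcm3 at -0.48 (SE 0.05) and Mcm2 at -0.43 (SE 0.04). Of the G2 and M phase genes 17 of 24 rose (18 adjusted over the list alone) and 0 fell, with the mitotic kinesin Kif20a at 0.62 (SE 0.06), the anaphase activator Cdc20 at 0.59 (SE 0.05) and the mitotic cyclin Ccnb2 at 0.36 (SE 0.03). The counts of the early T cell receptor, Th2, MYC, sterol, ATF4, glycolysis and G1 and S phase lists were the same when adjusted over the list alone.

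Type I interferon genes rose over the same hours. In the type I list 53 of 62 rose and 1 fell (55 and 2 adjusted over the list alone), at 0.61 ± 0.25 (SD, n = 7 pairs, 1.52-fold), higher at 8 h with 7 of 7 inhibitors. Ifit3 rose by 1.45 (SE 0.17), Oas3 by 1.52 (SE 0.11), Ifi213 by 1.52 (SE 0.09), Herc6, an ISG15 ligase, by 1.35 (SE 0.10), Ms4a4c by 1.28 (SE 0.06), Ifi27l2a by 1.24 (SE 0.07), Irf7 by 1.13 (SE 0.13), Ifit1 by 0.91 (SE 0.14), Epsti1 by 0.90 (SE 0.06), the nuclear body protein Sp100 by 0.86 (SE 0.04), Mx1 by 0.85 (SE 0.13), Stat2 by 0.42 (SE 0.10) and Irf9 by 0.20 (SE 0.05). Without the inhibitor as a block, 5772 genes passed and Ifit1, Mx1, Stat2 and Irf9 did not. Other large rises were in Ceacam1, an inhibitory adhesion receptor (1.67, SE 0.10), A530021J07Rik (1.61), the peptidoglycan sensor Nod1 (1.45), Cd226, an activating receptor (1.41), and Zbtb7b, the CD4 lineage factor ThPOK (1.35). The mean of the GTPase list fell with 7 of 7 inhibitors, at -0.15 ± 0.07 (SD, n = 7 pairs, exact sign-flip p = 0.0156, adjusted p = 0.0223), although 6 of 22 members were higher and 6 lower, also when adjusted over the list alone, and camera gave 0.789: Irf8 fell by 1.34 (SE 0.07), Gbp5 by 1.19 (SE 0.06) and the checkpoint ligand Cd274 by 1.15 (SE 0.06), while Tapbp, of peptide loading, rose by 0.37 (SE 0.04). Of the JAK and receptor genes, Jak1 rose by 0.31 (SE 0.04), Tyk2 by 0.35 (SE 0.06) and the receptor chain Ifnar2 by 0.49 (SE 0.04), while Jak2 fell by 0.38 (SE 0.04) and Ifnar1 by 0.22 (SE 0.04). Of the feedback genes Socs1 fell by 0.72 (SE 0.06) and Socs3 was at -0.09 (SE 0.09, adjusted p = 0.443).

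Of the 11761 genes tested, 2517 rose and 3313 fell (limma, adjusted p under the 0.05 threshold), and 4524 moved the same way with all 7 inhibitors (38.5%, where chance gives 1.56%), 4350 of them called. Which direction held more genes turned with the scaling: 3239 rose and 3126 fell after quantile normalization, 3312 and 3025 after median centring, and 3074 and 3318 after cyclic loess. With a fold change of at least 1.5 required, 923 passed. Camera called 18 of 30 lists at the preset correlation and 0 of 30 with an estimated one, where the adjusted p was 0.159 for the early T cell receptor, STAT5-induced, Th2, MYC and ATF4 lists, 0.199 for sterol synthesis, 0.274 for the type I list and for glycolysis, 0.416 for G2 and M phase and 0.46 for G1 and S phase. Fry called 24 of 30. The two-sided exact sign-flip p was 0.0156, the smallest 7 pairs allow, for each of these 10 lists (adjusted p = 0.0223). B cell markers were higher at 8 h beside these groups, with Ms4a1 up by 0.78 (SE 0.07) and Cd79a by 0.51 (SE 0.08), and so was Cd74 (0.35, SE 0.05). T cell markers rose too, with Thy1 at 0.47 (SE 0.04), Cd3d at 0.46 (SE 0.04) and Cd4 at 0.35 (SE 0.04), 9 of 12 in all.

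**Figure D3:**
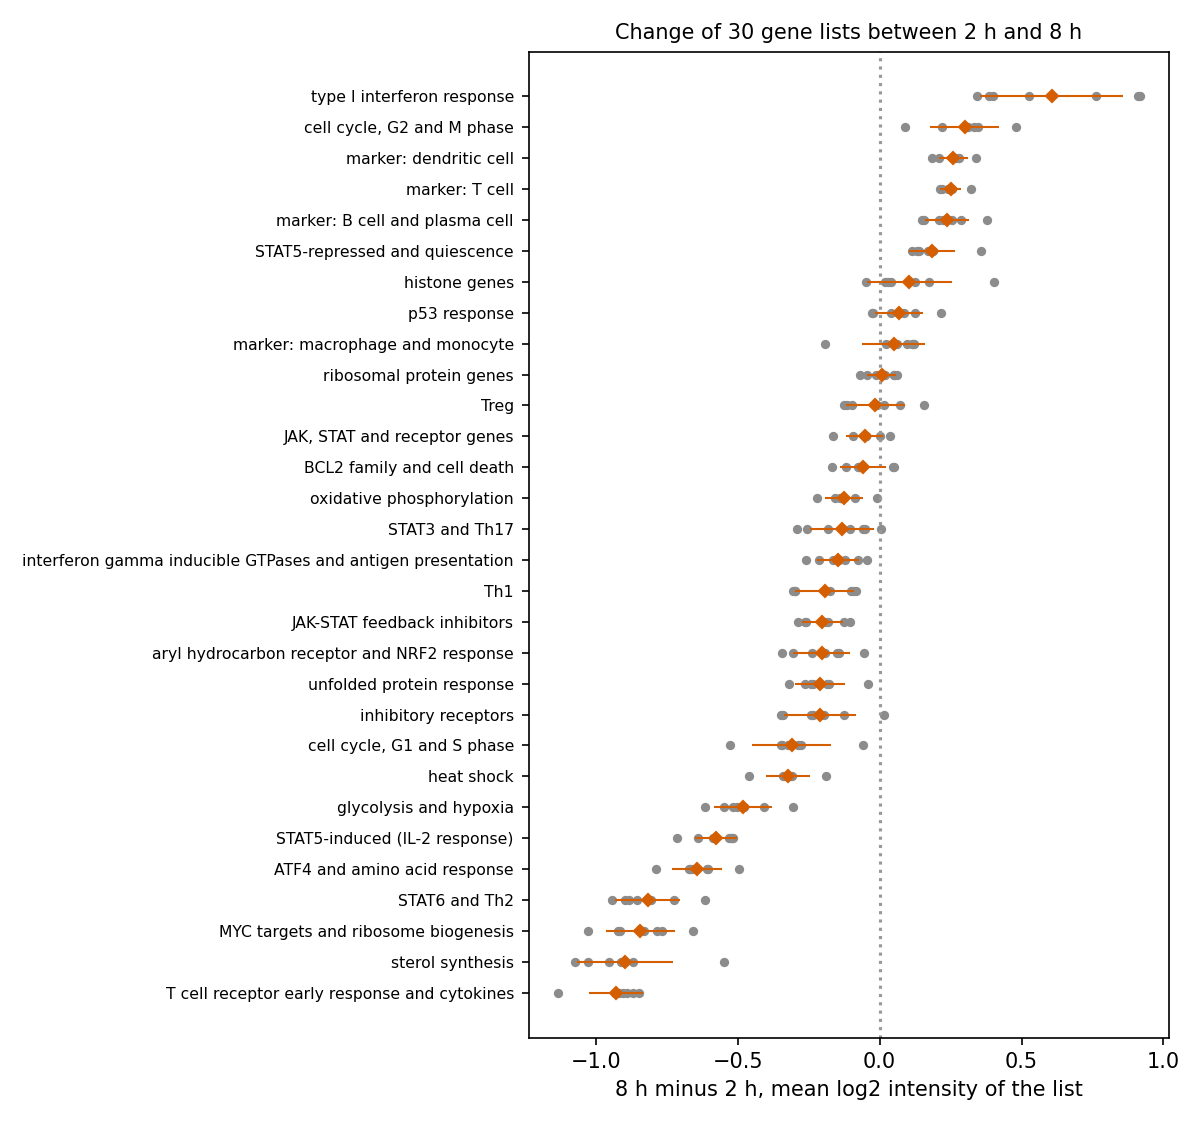
Change of each of 30 gene lists from 2 h to 8 h in mean log2 intensity (x axis), with 1 grey point per inhibitor (n = 7) and an orange diamond and bar for their mean and SD. The type I interferon list is at 0.61 and the early T cell receptor list at -0.93; the signs of the Treg list (-0.02) and of the JAK, STAT and receptor genes (-0.05) turn or reach 0 under another scaling.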

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

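The tests with cyclic loess, of the lowest 2 h values, of the dimmer and brighter members and of the narrowing without the JAK1 inhibitor, and the muscle list, were chosen after the results were seen. In groups of 7 arrays, a gap test (Dixon) picks about 1 in 20 groups by chance, and it picked 5 of 68 here. The mean of the type I interferon list at 8 h was 8.888 with the JAK1 inhibitor, far below the nearest other array (9.739). That of the STAT5-induced list at 8 h was 9.263 with the JAK2 inhibitor (nearest 9.03). That of the G2 and M phase list at 2 h was 10.45 with the JAK2 inhibitor (nearest 10.54), and that of the JAK, STAT and receptor genes at 2 h was 10.19 with the TYK2 inhibitor (nearest 10.25). The skeletal muscle list at 2 h was 7.63 with the JAK1/2 inhibitor (nearest 7.174). The change from 2 h to 8 h differed between the target classes in 12 genes, by a test of the difference itself.

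The type I interferon list was lowest with the JAK1 inhibitor, and 88% of the genes that passed there were lower. A brightness-dependent difference of its 8 h array is argued against as the whole cause of the lower interferon list, which was at -1.047 as deposited and at -0.960 after cyclic loess removed that trend. The 8 h array alone is argued against too, since at 2 h 50 of the 62 members also had their lowest value in the JAK1 array. The members move together on the same 7 arrays, so 1 in 7 of them (8.86) is no measure of chance. The excess of lower calls has no test of its own, since a scaling that centres the genes balances the directions: after cyclic loess 783 genes were lower and 774 higher, against 801 and 113 as deposited. A stronger block of JAK1 by this inhibitor at its IC80 stays open for the list and was not tested.

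The gap in the type I list between the classes narrowed from 2 h to 8 h by 0.403. A ceiling of bright probe sets is argued against: the median narrowing was 0.403 in the dimmer members (27 of 31 positive) and 0.413 in the brighter (29 of 31). The deviating 8 h array of the JAK1 inhibitor is the lowest in this list, which widens the gap at 8 h and so works against a narrowing. Without that inhibitor the narrowing was 0.487, where the SD of the 4 inhibitors was 0.183. Given the low value, this run could hardly have shown that array as the cause. A loss of inhibition over the hours may underlie the narrowing as a hypothesis, and so may a response that reaches its maximum earlier in the other class. Neither was tested, as the design has no other times.

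With the JAK2 inhibitor 9 genes were higher, among them Cish, Socs1 and Socs2. A brightness-dependent difference of its arrays is argued against as the source of the size of their difference, at a median of 0.652 as deposited and 0.618 after cyclic loess. Their calls ended there except that of Socs2: Cish went from 1.06 (SE 0.14) to 1.02 (SE 0.17) and Gbp11 from 0.53 (SE 0.08) to 0.49 (SE 0.07), the SE rose in 6 of the 9 and fell in 3, the prior degrees of freedom fell from 7.92 to 5.71, and which of these ended a call was not tested. For the 3 growth and sterol lists at 8 h (MYC target, sterol and G1 and S phase genes), higher by 0.296 as deposited and 0.158 after cyclic loess, the trend and the inhibitor cannot be told apart, because the value lies between what each would give. Whether weaker inhibition of JAK1 and JAK3 at this dose raised the STAT5 targets is open and was not tested.

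Chance is argued against for the 5830 genes that differed between times: 1 of 100 drawn splits of the 14 arrays, the real one, gave as many, and the highest other gave 3250. Among the 64 splits that keep 1 array of each inhibitor on each side, and so part all 7 pairs as the real one does, again only 1 did (highest other 2186), while the other drawn splits parted at most 5 pairs. For the classes, 35 splits of the inhibitors into 4 and 3 were counted. Only the real split gave as many as the 82 genes at 2 h (1 of 35 splits, highest other 0). The same held for the 12 genes of the 8 h minus 2 h difference (1 of 35, highest other 6, for the JAK1, JAK2 and both JAK3 inhibitors against the rest). No share below 1 in 35 can be reached, and the mean and the 8 h values were tried besides, so chance is not excluded for either count. For the mean and at 8 h the real count is 0, which all 35 of 35 splits reach by construction (highest other 1 and 0), so these counts say nothing about chance.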

How the results depend on the processing

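Cyclic loess and the runs without the JAK1 8 h array were chosen after the data were seen, and all listed alternatives could be run; the cause of a change was not tested unless given. The 0 genes of the comparison of JAK1 or JAK3, of the PAN inhibitor and of the classes at 8 h stayed at 0 under every alternative run. Quantile normalization gave 24 genes for the class difference of the 8 h minus 2 h change, 1538 for the JAK1, 1 for the JAK2 and 2 for the TYK2 inhibitor. Median centring gave 25, 1457, 2 and 5, and 0 for the JAK1/2 inhibitor. Cyclic loess gave 26, 1557, 2 and 6. With no filter the class mean had 1 gene and the JAK1/2 inhibitor 2. With the 60th percentile the JAK1/2 inhibitor had 0 and the TYK2 inhibitor 2. With no variance trend 103 genes differed between any inhibitors and 4 with the JAK2 inhibitor. Robust moderation gave 46 genes between the classes at 2 h, and the offset of 50 gave 7 for the class difference of the change. A fold change of at least 1.5 left 923 genes for time and 125 for the JAK1 inhibitor, since it adds a condition. Without pairing by inhibitor (no block) 5772 genes differed between times. With the inhibitor as a random block the class mean had 64 genes, at a consensus correlation of -0.023, which treats the 14 arrays almost as independent. With the JAK3 inhibitors averaged, 33 genes differed between the classes at 2 h and 2 in their change. With an estimated correlation camera called 3 list shifts over all comparisons in place of 118.

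Leaving out each inhibitor or the JAK1 8 h array gave 4987 to 6434 genes for time, 45 to 218 between any inhibitors, 0 to 98 for the class mean, 28 to 106 for the classes at 2 h, 2 to 41 for their change, 232 to 1528 for the JAK1, 4 to 81 for the JAK2, 0 to 16 for the JAK1/2, 0 to 6 for IFN.6226, 0 to 25 for IFN.6228 and 0 to 7 for the TYK2 inhibitor, 6 to 18 pairs with any gene, and 93 to 112 list shifts. The class difference of the type I list stayed negative, from -0.792 to -0.500 for the mean, -0.971 to -0.744 at 2 h and -0.614 to -0.257 at 8 h, with an exact p at its smallest each time, which fewer inhibitors raise. That of the STAT5-induced list at 2 h was -0.271 to -0.105, and -0.258 with list medians, where p was 0.0952.

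Some list changes over time turned sign, and not all of them were small. The Treg list was at 0.032 after quantile normalization, 0.038 after median centring, 0.019 after cyclic loess, 0.063 with scaled members, 0.003 without the JAK1 and 0.001 without the JAK1/2 inhibitor (from -0.044 to 0.003 over those left out). The JAK, STAT and receptor genes were at 0.000 after median centring and 0.019 with list medians. The ribosomal protein genes were at -0.001 without the JAK1 inhibitor (to 0.020 without PAN) and -0.012 with list medians. List medians, the level of the middle member in each array, also gave 0.091 for Th1 (list mean -0.194) and 0.152 for inhibitory receptors (list mean -0.210). They gave 0.035 for heat shock (list mean -0.324) and -0.109 for p53 genes (list mean 0.069). For the class difference in the change of the GTPase list they gave -0.004. Signal over background limits dim genes, which were not tested.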

Other observations

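The tests in this part were among those fixed, except that cyclic loess, the muscle list and the platelet values were chosen after the data were seen. Several gene groups not described so far changed between 2 h and 8 h. Genes of quiescence that STAT5 represses rose in 10 of 20 cases and fell in 4, at a mean of 0.18 ± 0.08 (SD, n = 7 pairs), with Pik3ip1, a brake on PI3 kinase, up by 1.06 (SE 0.05) and the exchange factor Rasgrp2 by 0.91 (SE 0.07). Camera gave an adjusted p of 0.0147, and the adjusted p = 0.517 with an estimated correlation. In the heat shock list 10 of 13 fell and 0 rose, with the mitochondrial chaperonin Hspd1 at -0.67 (SE 0.04; camera 2.67e-04, adjusted p = 0.265 with an estimated correlation). In the unfolded protein response list 12 of 18 fell and 3 rose, with the transcription factor Xbp1 at -0.60 (SE 0.04) and the chaperone Hspa5 at -0.52 (SE 0.05; camera 0.0172, adjusted p = 0.517 with an estimated correlation). In the oxidative phosphorylation list 15 of 27 fell and 1 rose, with Cyc1 at -0.46 (SE 0.06; camera 0.0147, adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone, these counts were the same, but for 11 rises among the quiescence genes.

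T helper genes split. Of 13 Th1 genes 6 rose and 5 fell, with the chemokine Ccl5 up by 0.79 (SE 0.06), the interleukin-12 receptor chain Il12rb2 down at -1.35 (SE 0.08) and the factor Runx3 at -1.14 (SE 0.06; camera 0.789, adjusted p = 0.87 with an estimated correlation). Of 12 Treg genes 5 rose and 4 fell, with the actin-capping protein Capg up by 0.72 (SE 0.05) and the ecto-nucleotidase Nt5e at -0.96 (SE 0.08); the sign of their mean (-0.02) turns with the scaling. Of 18 p53 response genes 6 rose and 4 fell (7 and 4 adjusted over the list alone), with the stress gene Sesn1 up by 0.64 (SE 0.06; camera 0.257). With the JAK1 inhibitor the ribosomal protein list was at -0.15 (6 of 23 lower, 9 adjusted over the list alone), and at -0.11 after cyclic loess, with Rps14 at -0.38 (SE 0.07) and Rps20 at -0.27 (SE 0.05), neither past the threshold after median centring. Camera gave 0.00135, and the adjusted p = 0.412 with an estimated correlation.

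The mean of 15 skeletal muscle genes was between 7.55 and 7.63 in 3 arrays, those of the JAK1/2 inhibitor at 2 h and 8 h and of the JAK1 inhibitor at 8 h, and between 6.90 and 7.18 in the other 11. All 3 belong to the class naming JAK1 or TYK2, no label gives a batch or day, and whether these arrays were handled apart is not known. Without the JAK1/2 inhibitor, the only one of that class with such an array at 2 h, 68 genes differed between the classes at 2 h (82 with it) and the type I list by -0.941. Ppbp, a platelet gene, ranged from 6.22 to 9.42 over the 14 arrays.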
